A study of Mus musculus with 8 samples.

How the data were processed

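Total RNA from mouse testis, frozen and extracted with Trizol, was made into sequencing libraries with an Illumina TruSeq kit, per the labels' protocols. The table analysed here holds FPKM values for 55414 Ensembl genes in 8 samples, 4 control and 4 valine, as deposited by the authors. Reads were aligned with HISAT2 to the mouse assembly GRCm39, per the submitters' processing notes; the version of the aligner, the quantifier, the strand setting and the annotation release were not given in the sources used here. FPKM divides fragments by gene length and by the mapped fragments of the library, so a change in the average length of the sequenced transcripts changes every value of a sample together. Columns were assigned to samples by the group name or abbreviation and replicate number in their headings, with 0 per-sample columns left unused.

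Low values were checked for whole-fragment steps. In 70.2% of 2799 genes with low values, the 8 values scaled by relative depth were whole multiples of a common unit (tolerance 0.03 fragments plus a small allowance that grows with the multiple), against 0.214% when random noise was added to the values. This gave each sample's depth relative to control replicate 1. No absolute depth was derived, because the gene lengths used by the authors were not given in the sources used here. No pair of samples held identical values.

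Gene symbols were taken from tables of the GENCODE vM21 and RefSeq GRCm38.p6 annotations by Ensembl identifier, which named 52081 of the 55414 genes and left 3333 by identifier. List members with newer symbols were matched through synonyms. Exon length (the union of a gene's exons), GC content of its longest transcript and gene type came from GENCODE vM21; a length was found for 21688 of the tested genes (98.2%). That annotation is of an older assembly than the authors' and no coordinates were used.

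The values were analysed as log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 8 samples were tested (22077 genes) with limma version 3.58.1 in R 4.3.3, in a model with treatment as its only term, empirical Bayes moderation with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The 35 gene lists were fixed before the data were examined: 14 of cell types, 3 of RNA quality and 18 of pathways; any pair of lists shared at most 2 members. Each list was tested with camera on the same values with a preset correlation of 0.01, adjusted over the 35 lists. Members were counted with the adjustment over all tested genes and with the adjustment over the list alone. Per-sample means were compared by two-sided exact permutation tests over the 70 arrangements of 4 against 4 samples, with 0.0286 as the smallest p they can give.

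Genes were named by a rule fixed before the data were examined. It took the 15 largest rises and the 15 largest falls among genes past the threshold, with no overlap between the groups and a symbol that is not a clone or model name. For each list it took up to 4 members past the threshold by size of change, or the 2 with the smallest p where none passed. It also took 17 genes of valine breakdown, autophagy, apoptosis and methylation fixed by name. The rule gave 136 genes, not all of which are named in the text; others are said to have been chosen after their values were seen.

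The same tests were repeated with a pseudocount of 0.1, no expression filter, a filter at a mean of 5 FPKM, rescaling to equal totals, equal medians, quantile normalisation, array weights, moderation without the trend, robust moderation, the replicate number as a block, leaving out each sample, camera with an estimated correlation, and fry. Removal of a smooth trend on gene length or on GC content, fitted for each sample with a loess span of 0.3, was added after the data were seen. The fit was tested on simulated data for the comparison of valine with control over 22077 genes, 200 of them changed. It recovered 26.0% of 100 genes changed by 0.5 on the log2 scale and 74.0% of 100 genes changed by 1, with 4 false calls among 104. The labels give no batch.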

Results

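Testes of mice given valine, a branched-chain amino acid, and of control mice were compared by RNA sequencing. The labels placed 4 samples in each group, and expression was given as FPKM (fragments scaled by transcript length and mapped fragments) for 55414 genes. The dose, route and length of treatment, and whether each sample came from a separate animal, were not given in the sources used here, so the p-values measure only the spread between these samples, which may be technical. The FPKM totals lay between 944659 and 974626 in the 4 control samples and between 1027660 and 1070520 in the 4 valine samples. Low FPKM values stood in whole-number ratios between samples, which gave a sequencing depth relative to control replicate 1 of 0.870 to 1.00 in the control group and 0.866 to 0.991 in the valine group. The absolute depth was unknown. Rank correlations across genes (Spearman's rho; genes are not independent replicates) were 0.916 to 0.922 within groups and 0.914 to 0.921 between groups. The first principal component held 26.0% of the variance, with scores of -36.84 to -6.34 in the control samples and 13.71 to 31.19 in the valine samples.

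The comparison asked how valine changed the transcripts of the testis, with apoptosis, autophagy and nucleic acid methylation named in the series title. The largest falls included enzymes of steroid hormone synthesis. Cyp11a1, the enzyme that cleaves the side chain of cholesterol at the start of steroid synthesis, fell from 115.5 ± 29.7 FPKM in control to 19.0 ± 3.78 FPKM in valine testes (mean ± SD, n = 4 per group). This was a 5.75-fold fall. Scd1, a fatty acid desaturase, fell 5.82-fold, and the fatty acid receptor Cd36 fell 5.55-fold. Apart from Snord42b, which was listed at 0 in every control sample, transcripts that rose did so by less than the largest falls. Prm2, which packs DNA in the sperm head, rose from 11235 ± 106 to 15537 ± 1102 FPKM, a 1.38-fold rise that did not pass with quantile normalisation (limma adjusted p = 0.511). In all, 954 genes rose and 974 fell among 22077 tested genes at a limma adjusted p below 0.05, and 23 of the risen and 185 of the fallen genes changed by at least 2-fold. All fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

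The groups did not overlap for 1900 of these 1928 genes and for 4056 of all tested genes (18.4%), where chance gives 2.86%. The numbers of genes depended on the scaling of the samples. After rescaling to equal totals, which moved the median change of all genes by -0.10 on the log2 scale, 363 genes were higher and 2022 lower (15.2% higher, against 49.5% as deposited), and after quantile normalisation 398 were higher and 1029 lower (27.9% higher). With 1 library left out the counts were 381 to 795 higher and 461 to 802 lower. Both fell by over 1.5 times without control replicate 1 (381 and 461), control replicate 2 (466 and 562) or valine replicate 1 (410 and 489), 2 (593 and 578), 3 (629 and 647) or 4 (580 and 614).

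The 15 largest falls among named genes ranged from -2.54 to -1.88 on the log2 scale. After Scd1, Cyp11a1 and Cd36 they comprised Sult1e1 (estrogen sulfotransferase; 58.0 ± 20.7 to 9.35 ± 2.98 FPKM, log2 change -2.50 ± 0.295 SE, limma adjusted p = 0.00408), 3 steroidogenic enzymes (Hsd17b3, Hsd3b1 and Cyp17a1), Ces1d, Selenop, C1ra, Bhmt, Ephx1, Mir7222, Itih2 and Ugt1a6b. Selenop, the plasma selenium carrier, fell from 60.4 ± 11.2 to 14.0 ± 2.49 FPKM (limma adjusted p = 0.00116). Ephx1, the microsomal epoxide hydrolase, fell from 136.1 ± 31.1 to 34.8 ± 7.09 FPKM (limma adjusted p = 0.00278). Ces1d and Ugt1a6b have close paralogs, and their values are uncertain where reads were split between copies. Mir7222 is a very short gene, for which few fragments can give a high FPKM, so its values are uncertain too.

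Among the 15 largest rises, Snord42b, a small nucleolar RNA, was listed at 0 in every control sample and at 8.73, 8.12, 5.71 and 3.93 FPKM in valine replicates 1 to 4 (limma adjusted p = 0.00116). The other 14 rose by at most 1.14 on the log2 scale. Mt4, a metallothionein, had 0.903 ± 0.514 FPKM in control and 3.25 ± 1.39 FPKM in valine testes (limma adjusted p = 0.0452). Tslrn1 rose from 21.0 ± 2.46 to 35.8 ± 3.23 FPKM (limma adjusted p = 0.00557). Others were Taco1os, Rpl36-ps12, Olfr761, Rab3b, Mob3b, Upk3bl, Particl, Epb41l4aos, Hist1h2bl, Jsrp1 and Speer4e. Antisense transcripts and copies of gene families among them are uncertain, since the strand setting of the counting was not given in the sources used here. The values of Snord42b are uncertain too, since FPKM divides by length and few fragments of a very short gene can give a high value. After removal of the length trend, calls such as those of Epb41l4aos and Hist1h2bl were lost (limma adjusted p = 0.0636 and 0.0707).

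Leydig cells, the testosterone-producing cells between the tubules, showed the largest change of any list fixed before the data were examined. Of 17 Leydig and steroidogenesis genes 14 fell and none rose (15 fell when adjusted over the list alone), with a list median of -1.55 on the log2 scale. Cyp17a1, which makes androgen precursors, fell from 415.7 ± 108 to 95.4 ± 17.7 FPKM (log2 change -2.09 ± 0.216 SE, limma adjusted p = 0.00299). Hsd17b3, which makes testosterone, fell from 87.1 ± 25.8 to 16.5 ± 6.21 FPKM (log2 change -2.36 ± 0.284 SE, limma adjusted p = 0.00426), and Hsd3b1 from 127.9 ± 44.7 to 28.0 ± 3.52 FPKM (log2 change -2.10 ± 0.221 SE, limma adjusted p = 0.0032). The 3 members that did not pass, named after their values were seen, were Hsd3b6 (77.2 ± 32.6 and 24.4 ± 7.90 FPKM), Tspo (11.95 ± 2.06 and 9.54 ± 1.84 FPKM) and Nr4a1 (33.6 ± 4.29 and 33.2 ± 2.43 FPKM). Hsd3b1 and Hsd3b6 are near-identical paralogs and their split is uncertain. The list was lower relative to other genes (camera with a preset correlation of 0.01, adjusted p = 2.61e-16 over 35 lists), and not past the threshold with an estimated correlation (adjusted p = 0.16).

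**Figure D1:**
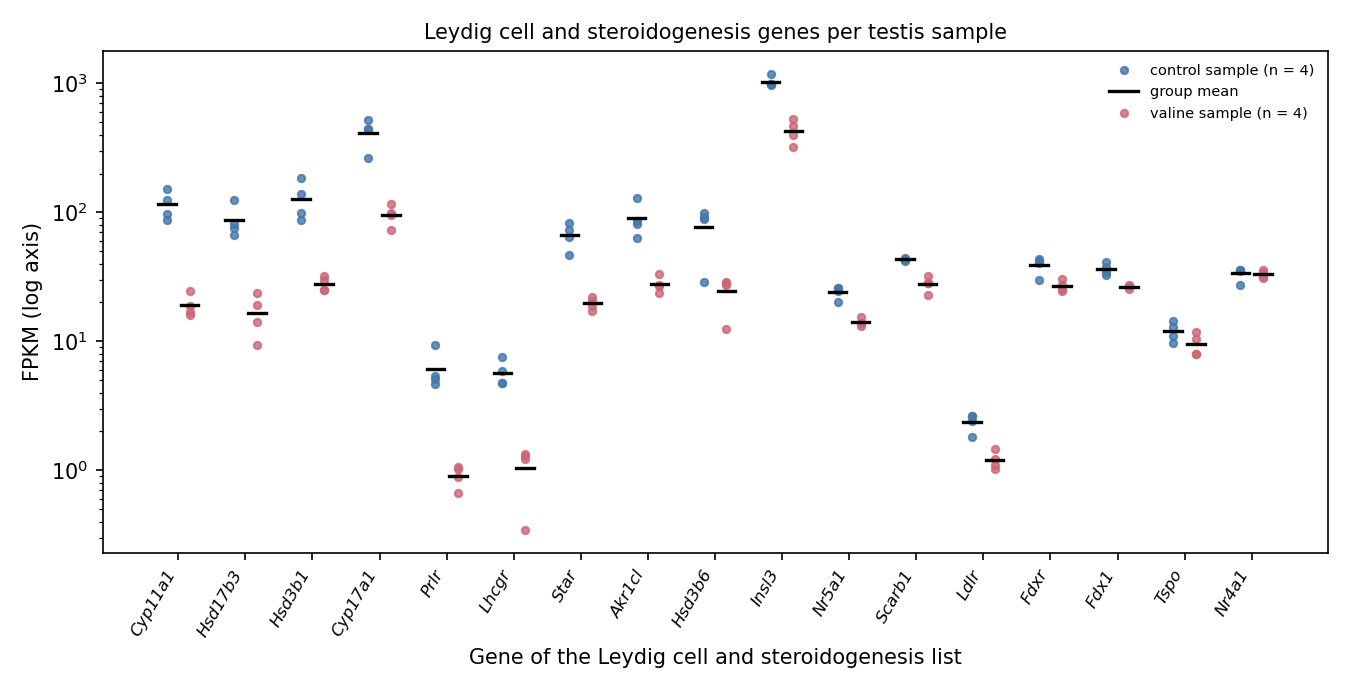
FPKM (log axis) of the 17 Leydig cell and steroidogenesis genes in each of the 4 control and 4 valine samples, ordered by log2 change; points are samples and black bars group means. The genes on the left are lower in every valine sample than in every control sample, as for Cyp11a1 (115.5 and 19.0 FPKM on average), and Nr4a1 on the right has means of 33.6 and 33.2 FPKM.

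Transcripts of other cells that lie between or around the tubules also fell. Of 17 stroma and extracellular matrix genes 11 fell and none rose (13 fell when adjusted over the list alone), among them Col4a1 (10.2 ± 2.77 to 3.20 ± 0.562 FPKM), Col4a2, Col1a2 and the proteoglycan Dcn (17.2 ± 3.01 to 6.47 ± 1.17 FPKM). Of 15 macrophage genes 6 fell and 1 rose (8 and 1 when adjusted over the list alone). Lyz2 (36.7 ± 5.96 to 13.3 ± 0.686 FPKM), Ctss, Csf1r and C1qa were among the falls, and Aif1, named after its value was seen, rose by 0.32 on the log2 scale. Of 9 endothelial genes 4 fell (Eng, Esam, Cdh5 and Cldn5; 5 when adjusted over the list alone), and of 13 peritubular myoid genes 3 fell (Acta2, Cald1 and Lmod1; 5 when adjusted over the list alone). These 4 lists had medians of -0.73, -0.58, -0.38 and -0.39 and camera adjusted p values of 2.07e-09, 1.33e-06, 6.7e-05 and 3.76e-05; with an estimated correlation the adjusted p values were 0.161, 0.16, 0.132 and 0.161.

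Markers of cells that can enter a testis sample from outside or from blood had few calls. In the adipocyte list 1 of 7 tested genes fell (Plin1; 2.21 ± 0.760 to 0.664 ± 0.222 FPKM; 1 when adjusted over the list alone), 6 had a negative change, and the median was -0.60 on the log2 scale (camera adjusted p = 0.0623, and 0.0136 without an expression filter, 0.0332 with a pseudocount of 0.1 and 0.0306 after removal of the length trend). The list mean was 3.21 in control replicate 1 and 1.49 to 2.02 in the other control samples. Cfd and Car3, named after their values were seen, had 29.8 and 14.6 FPKM in control replicate 1, 0.325 and 0.261 FPKM in control replicate 2, and means of 0.038 and 0.0608 FPKM in valine testes (limma adjusted p = 0.212 and 0.197). Scd1 had 25.8 and 25.6 FPKM and Cd36 25.01 and 18.5 FPKM in control replicates 1 and 2. In the epididymis list 1 of 2 rose (Cst8; 357.3 ± 8.37 to 447.7 ± 49.5 FPKM; 1 when adjusted over the list alone; camera adjusted p = 0.159). Cst8 did not pass with equal totals, after removal of the length trend or with quantile normalisation (limma adjusted p = 0.086, 0.197 and 0.161). Only 2 of the 13 epididymis genes passed the expression filter, so the list could hardly check for epididymis. Cst8 was abundant in every sample while most of the list was below the filter, so its rise is no measure of epididymis. None of 6 red blood cell genes and none of 3 lymphocyte genes passed, also when adjusted over the list alone (camera adjusted p = 0.585 and 0.964). Hba-a1 had 31.2 ± 10.7 FPKM in control and 20.8 ± 14.7 FPKM in valine testes and Slc4a1 0.881 ± 0.0606 and 1.14 ± 0.127 FPKM. Cd3d had 11.001 ± 1.21 and 13.8 ± 2.35 FPKM and Ighm 2.32 ± 0.850 and 1.28 ± 0.111 FPKM.

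Germ cell genes that rose were mostly those of spermatids. Of 24 elongating spermatid and sperm tail genes 16 rose and none fell (19 rose and 1 fell when adjusted over the list alone; median 0.25 on the log2 scale, camera adjusted p = 8.9e-11). Prm1 rose from 10342 ± 289 to 14362 ± 1878 FPKM, Tnp1 from 3244 ± 194 to 4543 ± 537 FPKM and Prm3 from 396.2 ± 24.9 to 574.4 ± 58.2 FPKM; protamines and transition proteins replace histones in the sperm head. Prm1 and Tnp1 did not pass with quantile normalisation (limma adjusted p = 0.319 and 0.127) or after removal of the length trend (limma adjusted p = 0.0781 and 0.0645). Of 23 round spermatid and acrosome genes 6 rose, with Acrbp (119.2 ± 9.85 to 156.6 ± 5.29 FPKM), Tssk6 and Spaca7 among them, and 1, Tssk2, fell from 745.5 ± 36.9 to 508.9 ± 96.9 FPKM (9 and 1 when adjusted over the list alone; median 0.15, camera adjusted p = 0.000742). With an estimated correlation the adjusted p values of the elongating and round spermatid lists were 0.161 and 0.368, and with quantile normalisation 0.0654 and 0.47. The round spermatid list also did not pass after removal of the length trend (adjusted p = 0.057) or with fry (adjusted p = 0.0532), and 2 of its genes were higher with equal totals.

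Earlier germ cells and Sertoli cells, the somatic cells inside the tubules, showed few calls. Of 25 spermatocyte genes Ccna1 rose (146.4 ± 11.8 to 180.8 ± 14.7 FPKM) and the cohesin Stag3 fell (237.6 ± 11.4 to 187.2 ± 4.999 FPKM; 3 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.232). Ccna1 did not pass with equal totals, after removal of the length trend or with quantile normalisation (limma adjusted p = 0.169, 0.156 and 0.238). Of 16 spermatogonial genes the receptor Kit fell from 7.96 ± 1.71 to 3.60 ± 0.402 FPKM and Zbtb16 from 3.67 ± 0.943 to 1.496 ± 0.132 FPKM (2 when adjusted over the list alone; camera adjusted p = 0.405); Kit is also made by Leydig cells. Of 20 Sertoli genes Defb36 rose from 55.4 ± 4.06 to 74.0 ± 3.93 FPKM and Rhox8 from 15.9 ± 1.63 to 21.4 ± 2.01 FPKM (2 when adjusted over the list alone; camera adjusted p = 0.248). Neither passed after removal of the length trend (limma adjusted p = 0.0684 and 0.138), nor did Rhox8 with equal totals (limma adjusted p = 0.0847). Of 19 junction genes of the blood-testis barrier Cldn3 rose, and Cldn5, Ctnnb1 and Tjp1 fell (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.0734). Of these, Cldn3 (limma adjusted p = 0.138), Ctnnb1 (0.0548) and Tjp1 (0.238) did not pass after removal of the length trend, nor Cldn3 with equal totals (0.0724) or quantile normalisation (0.0719); the list passed downward with equal totals (adjusted p = 0.0247) and quantile normalisation (adjusted p = 0.0377). Of 21 genes of the piRNA pathway, which silences transposons in germ cells, Piwil2, Tdrd1 and Tdrd6 fell by 0.30, 0.28 and 0.215 on the log2 scale (3 when adjusted over the list alone; camera adjusted p = 0.307). None of the 3 passed after removal of the length trend (limma adjusted p = 0.052, 0.102 and 0.213), while the list passed downward with equal totals (7 lower, adjusted p = 0.0247) and quantile normalisation (adjusted p = 0.00548).

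**Figure D2:**
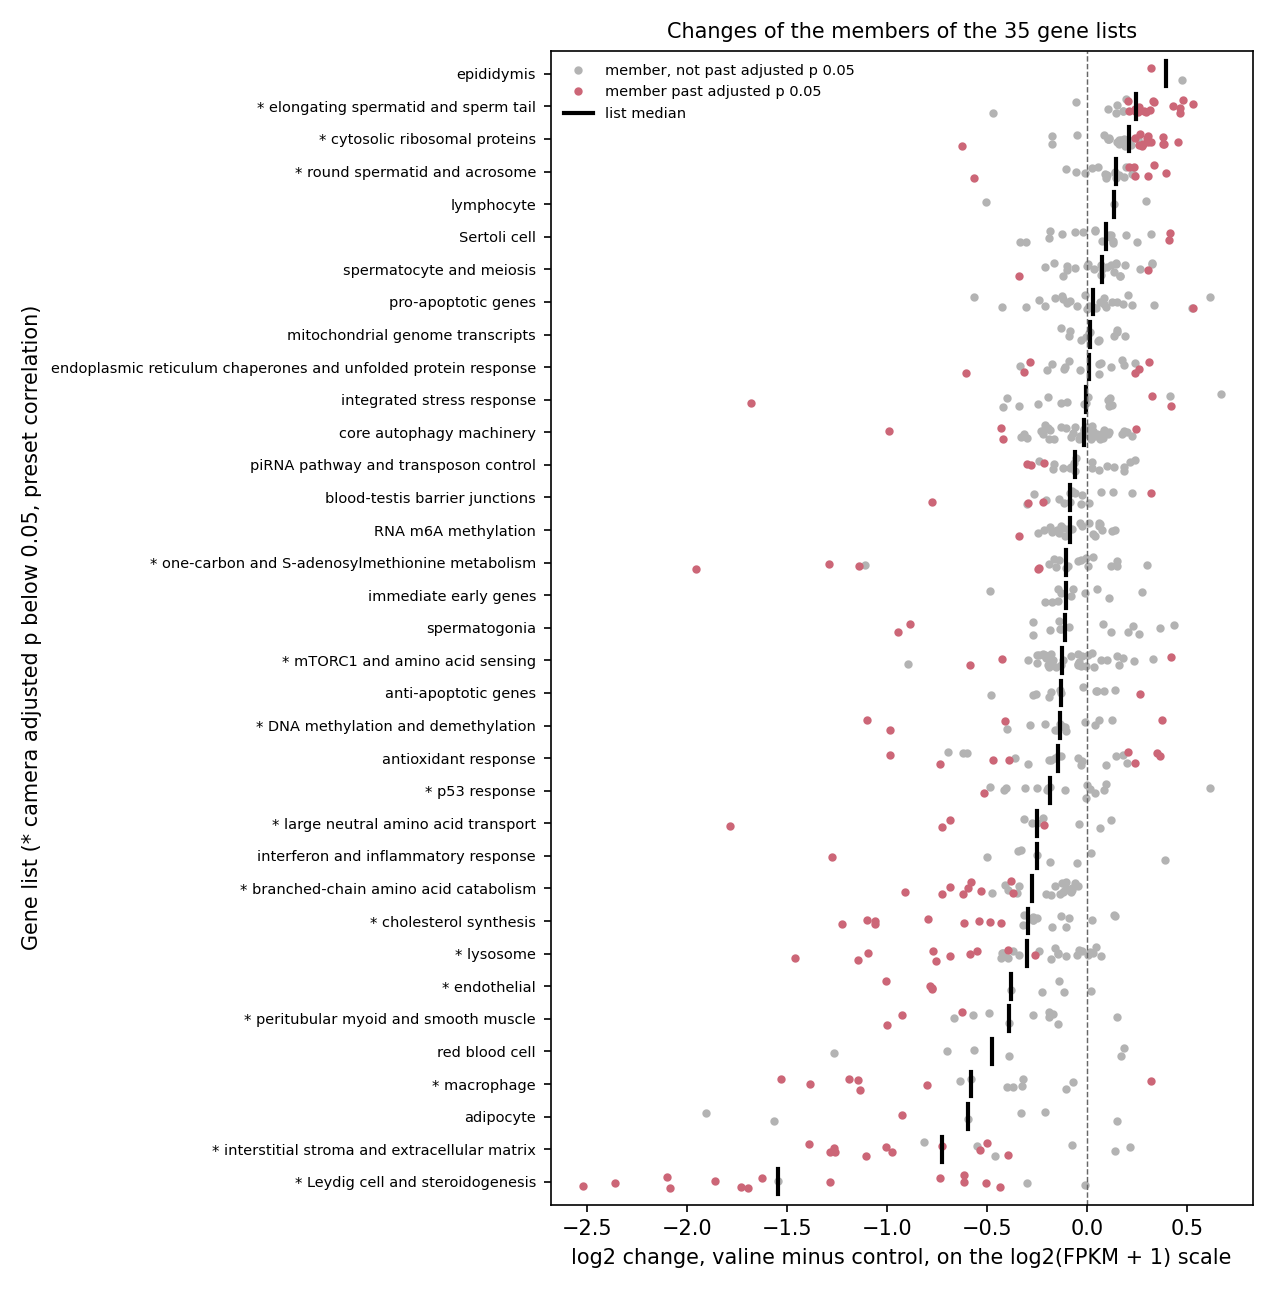
Log2 change (valine minus control, log2(FPKM + 1) scale) of every tested member of the 35 gene lists; red points passed an adjusted p of 0.05, grey points did not, black bars are list medians and asterisks mark lists past the camera threshold with the preset correlation. The Leydig list has the lowest median (-1.55), and the elongating spermatid list has a median of 0.25.

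Genes that rose were mostly short, and many were abundant. Tested genes were placed in 5 equal bins by exon length. In the shortest bin (12 to 807 bp) 218 rose and 38 fell, and in the longest (5782 to 41155 bp) 51 rose and 384 fell. The log2 change and the exon length correlated across genes with a Spearman's rho of -0.339. Among genes with a mean above 100 FPKM, 475 rose and 55 fell. With equal totals these numbers were 193 and 156 for the abundant genes, 122 and 71 in the shortest bin and 5 and 880 in the longest. The same direction was seen in RNA of ribosomal proteins, which are short: 13 of 35 rose and Rps4x fell (23 rose and 1 fell when adjusted over the list alone; 5 were higher and 1 lower with equal totals; median 0.21, and 0.09 with equal totals; camera adjusted p = 2.07e-09, and adjusted p = 0.164 with an estimated correlation), with Rps20 rising from 109.5 ± 7.54 to 150.4 ± 9.93 FPKM and Rpl23 from 138.4 ± 6.43 to 180.4 ± 2.71 FPKM. The ribosomal protein list was also among the 3 lists fixed as signs of RNA quality and handling. In the others, none of 13 mitochondrial genome transcripts and none of 12 immediate early genes passed, also when adjusted over the list alone (camera adjusted p = 0.485 and 0.409). The mitochondrial list passed downward with quantile normalisation (camera adjusted p = 0.01) and after removal of the length trend (camera adjusted p = 0.0352). mt-Co1 had 7984 ± 425 and 8750 ± 239 FPKM and mt-Co2 5582 ± 351 and 6368 ± 205 FPKM in control and valine testes. Btg2 had 3.95 ± 0.932 and 2.51 ± 0.328 FPKM and Ier2 5.92 ± 0.667 and 7.35 ± 0.644 FPKM.

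**Figure D3:**
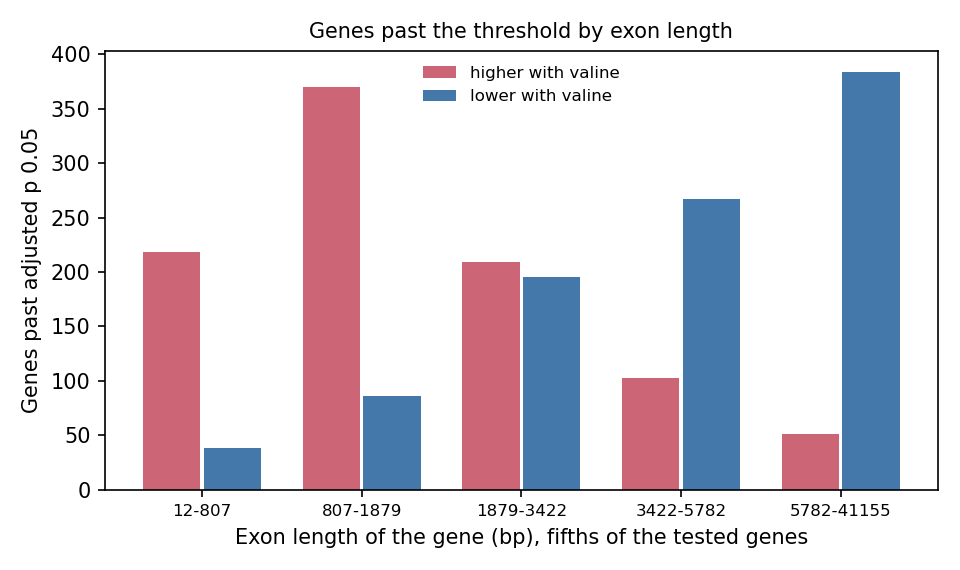
Number of genes past an adjusted p of 0.05 that were higher (red) or lower (blue) with valine, in 5 equal bins of the tested genes by exon length in bp. Higher genes outnumber lower genes 218 to 38 in the shortest bin, and lower genes outnumber higher genes 384 to 51 in the longest.

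Valine itself is broken down by the branched-chain amino acid pathway, and part of its genes fell. Of 28 tested members 9 fell and none rose (14 fell when adjusted over the list alone), all 28 had a negative change, and the median was -0.27 on the log2 scale (camera adjusted p = 4.88e-09; adjusted p = 0.161 with an estimated correlation). Acadm fell from 14.8 ± 3.46 to 7.26 ± 0.655 FPKM, Echs1 from 7.07 ± 1.35 to 3.84 ± 0.442 FPKM, Hsd17b10 from 18.4 ± 2.44 to 11.04 ± 1.06 FPKM and Ivd from 16.1 ± 2.48 to 10.03 ± 0.704 FPKM. Echs1 acts on the valine branch, Acadm and Echs1 also serve fatty acid oxidation, and Ivd acts on leucine. Acad8, Hibch, Hibadh and Aldh6a1 also act on the valine branch and were named after their values were seen. None of them passed (limma adjusted p = 0.0779, 0.71, 0.537 and 0.485). Of the first steps of the pathway, the transaminase Bcat2 did not pass, with 19.2 ± 2.03 and 18.5 ± 0.822 FPKM (limma adjusted p = 0.764). Of the branched-chain ketoacid dehydrogenase, Dbt, named after its value was seen, fell by 0.60 on the log2 scale (limma adjusted p = 0.0377), while Bckdha did not pass, with 25.5 ± 1.997 and 22.1 ± 3.41 FPKM (limma adjusted p = 0.284). Among 11 carriers of large neutral amino acids 4 fell (7 when adjusted over the list alone; median -0.25, camera adjusted p = 0.000185; adjusted p = 0.161 with an estimated correlation). Slc7a8 fell from 24.0 ± 5.81 to 6.24 ± 1.86 FPKM, Slc7a5 from 110.5 ± 12.5 to 66.2 ± 5.17 FPKM, its partner Slc3a2 from 82.9 ± 13.2 to 50.6 ± 3.16 FPKM, and Slc7a6 from 29.6 ± 0.226 to 25.4 ± 0.803 FPKM. The Leydig and interstitial lists fell in the same samples.

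In the mTORC1 list, which covers the kinase complex that senses amino acids, 2 of 40 genes fell and 1 rose, with the same counts when adjusted over the list alone. With equal totals 6 were lower and 1 higher. Mtor, the kinase, fell from 124.5 ± 5.02 to 82.5 ± 2.68 FPKM (log2 change -0.59 ± 0.047 SE, limma adjusted p = 0.00116), and Tsc2, an inhibitor of the complex, from 14.6 ± 0.712 to 10.6 ± 0.614 FPKM (limma adjusted p = 0.0104). Eif4ebp1, a translation repressor that the complex switches off, rose from 9.32 ± 0.673 to 12.8 ± 1.06 FPKM (limma adjusted p = 0.0208). The list passed with the preset correlation (median -0.12, camera adjusted p = 0.0109) and not with an estimated correlation (adjusted p = 0.161) or after removal of the length trend (adjusted p = 0.116).

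Autophagy genes did not move as a list. Of 46 tested genes 1 rose and 3 fell (3 and 5 when adjusted over the list alone; camera adjusted p = 0.175). Atg2a fell from 51.7 ± 17.2 to 24.5 ± 0.903 FPKM, Atg9a from 131.1 ± 9.83 to 97.7 ± 8.06 FPKM and Tecpr1 from 7.34 ± 1.05 to 5.15 ± 0.403 FPKM, while Gabarap rose from 333.5 ± 21.5 to 395.4 ± 8.06 FPKM. Gabarap did not pass with equal totals, after removal of the length trend or with quantile normalisation (limma adjusted p = 0.11, 0.101 and 0.201), nor did Tecpr1 after removal of the length trend or with quantile normalisation (limma adjusted p = 0.166 and 0.0563). Becn1 (34.3 ± 0.925 and 35.3 ± 1.97 FPKM), Map1lc3b (17.2 ± 0.799 and 16.97 ± 0.545 FPKM), Atg5 (7.09 ± 0.865 and 6.06 ± 0.448 FPKM) and Sqstm1 (60.3 ± 5.45 and 48.3 ± 5.31 FPKM) did not pass, with limma adjusted p values of 0.704, 0.909, 0.269 and 0.0726. With equal totals the list passed, downward (adjusted p = 0.00866), as it did after quantile normalisation (adjusted p = 0.0371). Lysosomal genes fell: 10 of 30 fell and none rose (18 fell when adjusted over the list alone; median -0.30, camera adjusted p = 1.23e-08; adjusted p = 0.132 with an estimated correlation), including the cathepsins Ctsh, Ctsb (30.6 ± 5.74 to 13.7 ± 1.72 FPKM) and Ctsd. Macrophages are rich in cathepsins, and their list fell in the same samples.

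Apoptosis genes showed few calls. Bik, a pro-apoptotic BCL2 family member, rose from 4.25 ± 0.729 to 6.56 ± 0.738 FPKM (limma adjusted p = 0.0377; 0.0584 with equal totals and 0.0943 after removal of the length trend), and was the sole call among 29 pro-apoptotic genes (0 when adjusted over the list alone; camera adjusted p = 0.927). Bax had 6.80 ± 0.781 and 7.04 ± 0.809 FPKM (limma adjusted p = 0.849). Among 13 anti-apoptotic genes Bag1 rose from 610.2 ± 32.6 to 732.4 ± 48.8 FPKM (1 when adjusted over the list alone; camera adjusted p = 0.387). Its call was lost with equal totals, after removal of the length trend and with quantile normalisation (limma adjusted p = 0.163, 0.227 and 0.301). Bcl2 was below the expression filter, with a mean of 0.185 FPKM over the 8 samples. In the p53 list 1 of 17 genes fell, Ccng1 (7.17 ± 0.661 to 4.73 ± 0.722 FPKM; 1 rose and 5 fell when adjusted over the list alone). The list passed with the preset correlation (camera adjusted p = 0.0331) and not with an estimated correlation (adjusted p = 0.161). It did not pass after removal of the length trend (adjusted p = 0.101), without genes below a mean of 5 FPKM (adjusted p = 0.172), or without control replicate 2 (adjusted p = 0.0562) or valine replicate 4 (adjusted p = 0.0603).

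Stress response lists held both rises and falls as deposited, and mostly falls with equal totals. In the integrated stress response list Gpt2 fell from 31.7 ± 4.89 to 9.22 ± 1.76 FPKM, and Ddit3 (45.2 ± 3.27 to 56.9 ± 5.26 FPKM) and Eif4ebp1 rose, of 19 genes (3 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.473; 1 higher and 4 lower with equal totals). Ddit3 did not pass with equal totals, after removal of the length trend or with quantile normalisation (limma adjusted p = 0.134, 0.155 and 0.0886). In the endoplasmic reticulum list 3 of 20 rose, Herpud1 (211.6 ± 3.21 to 263.3 ± 22.0 FPKM) among them, and Ern1, Sel1l and Edem1 fell (7 and 5 when adjusted over the list alone; camera adjusted p = 0.984; 1 higher and 5 lower with equal totals). Herpud1 did not pass with equal totals or quantile normalisation (limma adjusted p = 0.0825 and 0.178), Sel1l after removal of the length trend (limma adjusted p = 0.0871), and Edem1 after that removal or with quantile normalisation (limma adjusted p = 0.139 and 0.0538). Of 25 antioxidant genes 4 rose and 4 fell (5 and 7 when adjusted over the list alone; camera adjusted p = 0.136; 2 higher and 9 lower with equal totals). The falls were Gstm1 (388.1 ± 30.6 to 196.1 ± 25.5 FPKM), Gpx1 (38.9 ± 6.65 to 22.7 ± 1.49 FPKM), Prdx3 and Txn1. Among 9 interferon and inflammation genes Lcn2 fell from 96.5 ± 40.8 to 37.8 ± 10.2 FPKM (1 when adjusted over the list alone; camera adjusted p = 0.0721). The list passed without an expression filter (camera adjusted p = 0.00113), without control replicate 3 (camera adjusted p = 0.0331) and with fry (adjusted p = 0.0295).

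Among enzymes of nucleic acid methylation, Alkbh5, an eraser of the RNA mark m6A, fell from 33.8 ± 2.33 to 26.5 ± 2.60 FPKM (log2 change -0.34 ± 0.0815 SE, limma adjusted p = 0.0391; 0.0991 after removal of the length trend). It was the sole call among 24 m6A genes (0 when adjusted over the list alone; camera adjusted p = 0.159, and 0.00695, downward, with equal totals). The writers Mettl3 (9.73 ± 0.785 and 9.03 ± 0.776 FPKM) and Mettl14 (5.56 ± 0.208 and 4.77 ± 0.241 FPKM) and the eraser Fto (21.2 ± 0.997 and 22.1 ± 0.887 FPKM) did not pass (limma adjusted p = 0.538, 0.174 and 0.588). Of 18 genes of DNA methylation and demethylation 3 fell and 1 rose, also when adjusted over the list alone. Dnmt1, which copies DNA methylation after replication, fell from 25.7 ± 2.16 to 19.1 ± 1.49 FPKM (log2 change -0.41 ± 0.0832 SE, limma adjusted p = 0.0217; 0.0697 after removal of the length trend), and the methyl-CpG reader Mbd2 rose from 36.2 ± 1.79 to 47.4 ± 3.83 FPKM. Idh1 (67.4 ± 9.10 to 30.7 ± 0.778 FPKM) and Idh2, which are metabolic enzymes that supply the cofactor of demethylases, were the largest falls of that list. Dnmt3a did not pass (3.05 ± 0.285 and 2.72 ± 0.434 FPKM, limma adjusted p = 0.553), and Tet1 was below the filter with a mean of 0.228 FPKM. The list passed with the preset correlation (median -0.13, camera adjusted p = 0.0136) and not with an estimated correlation (adjusted p = 0.161), after removal of the length trend (adjusted p = 0.12) or with a filter at a mean of 5 FPKM (adjusted p = 0.0898).

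One-carbon metabolism, which supplies methyl groups, had 5 falls among 21 genes and no rise (6 fell when adjusted over the list alone; median -0.10, camera adjusted p = 0.00462; adjusted p = 0.161 with an estimated correlation and 0.0509 after removal of the length trend). Bhmt, which remethylates homocysteine, fell from 61.5 ± 23.4 to 14.7 ± 4.04 FPKM, Gnmt from 5.36 ± 1.97 to 1.52 ± 0.343 FPKM, Aldh1l1 from 16.7 ± 2.91 to 6.95 ± 0.537 FPKM and Ahcyl1 from 32.7 ± 2.32 to 27.4 ± 1.01 FPKM. Ahcyl1 did not pass after removal of the length trend (limma adjusted p = 0.165). Cholesterol synthesis, which feeds steroid synthesis, had 9 falls among 22 genes and no rise (10 fell when adjusted over the list alone; median -0.29, camera adjusted p = 1.5e-07; adjusted p = 0.161 with an estimated correlation). Sc5d, Msmo1 and Hsd17b7 fell by 1.23, 1.06 and 1.06 on the log2 scale. The Leydig list, with which the cholesterol list shares 1 gene, fell in the same samples.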

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

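The length correction, the counts of list members kept under rescaling, and the comparisons of list means, of 6 Leydig transcripts, of depth and of the correlation with length were chosen as tests after the data were seen; for the 3 tests after removal of the length trend, the bounds were written before those tests were run. A random grouping of these 8 samples is argued against by the number of genes past the threshold. Of the 35 splits into 4 and 4, only the real split, 1 of 35, gave 1928 genes or more. The highest of the others gave 24. The other splits mix the groups, which widens their spread, and 1 of 35 is the lowest share possible. Differences between the groups other than valine were not tested by these splits.

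Leydig cell genes were the strongest fall. The scaling of the deposited values did not account for it, since at least 14 of the 17 members stayed lower past the threshold under equal totals, equal medians and quantile normalisation. The transcript length trend did not either, since 13 stayed lower after its removal. Less interstitial tissue in the valine libraries as the whole account is argued against by the Leydig list mean. It fell by 0.736 more on the log2 scale than the mean of the macrophage, endothelial, stroma and myoid lists (exact permutation p = 0.0286, the smallest these samples can give, and lower in 4 of 4 samples). Those lists fell by 0.56 themselves, so a smaller interstitial share may account for part. Their members did not move alike: Ctss and Col4a1 changed by -1.53 and -1.39, and Aif1 and Postn by 0.32 and 0.22, on the log2 scale. The size of the gap therefore also depends on the genes in each list. Fewer Leydig cells with unchanged transcripts per cell would lower Leydig-restricted transcripts by a common factor, but 4 of 6 abundant ones departed from their mean. Cyp11a1 departed by -0.59 and Hsd17b3 by -0.43 (limma adjusted p = 0.000102 and 0.003), and Insl3 by 0.65 and Akr1cl by 0.30 (limma adjusted p = 5.95e-05 and 0.0311). All 6 genes were given the same SE (0.126) and came from the same 8 samples. Departures from a shared mean are also not independent, so these p values overstate the evidence. The unequal falls make a lower output of steroidogenic transcripts per Leydig cell after valine a hypothesis. A loss of cells in addition to it stays open.

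Genes higher with valine were mostly short transcripts. After removal of the length trend 475 genes were higher (376 of them among the original 954), less than 0.5 times the original number, so the length trend is a candidate explanation for many of the rises. Rescaling to equal totals left 363 higher genes, but it applies 1 factor to all genes of a sample and so can hardly move a rank correlation with length. The rho of the log2 change with exon length was -0.339 as deposited and -0.343 after quantile normalisation. A scaling that depends on the level of expression is therefore argued against as the source of the trend. Neither rescaling uses gene length, so the lengths within the FPKM values were not tested. A difference in sequencing depth is argued against by the mean relative depth, which differed by 0.00516 between the groups (exact permutation p = 0.943). Each sample's deviations correlated with exon length across genes at rho of 0.117 to 0.22 in the control samples and -0.258 to -0.113 in the valine samples, so whether the trend arose in the tissue or in the libraries remains confounded with the treatment.

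Elongating spermatid genes were higher with valine. After removal of the length trend 4 of the 16 called members stayed past the threshold, between the bounds written for the test. The list kept its camera call with the preset correlation (adjusted p = 7.8e-08, median 0.16 against 0.25), a call that as deposited was lost with an estimated correlation (adjusted p = 0.161), so the length trend cannot be told apart from a change in these genes for the single members. Under equal totals 8 of the 16 stayed and under equal medians 15, so the scaling of the deposited values cannot be told apart from a change for part of the members. Quantile normalisation left 2. It fixes the levels of the most abundant transcripts, so it decides nothing for members such as Prm1 and Prm2. A smaller share of interstitial cells would raise every germ cell list alike. The elongating list rose by 0.18 more on the log2 scale than the spermatocyte list as deposited (exact permutation p = 0.0286, higher in 4 of 4 samples) and by 0.175 more with equal totals (exact permutation p = 0.0286). It rose by 0.134 more after removal of the length trend (exact permutation p = 0.0857) and by 0.0464 more with quantile normalisation (exact permutation p = 0.343). The groups overlapped in both of these settings, so this explanation stays open. A larger share or output of late spermatids stays open and was not tested separately.

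Single samples stood apart from the other 3 of their group by Dixon's ratio (gap over range, critical value 0.830) in 25 of 404 groups checked, where chance gives about 20.2. In valine replicate 2, the stroma list mean (ratio 0.848; 2.34 against 2.22 to 2.24 on the log2 scale), Itih2 (0.914; 5.28 FPKM against 3.15 to 3.33), Col4a2 (0.874; 4.59 against 3.44 to 3.58) and Hba-a1 (0.89; 42.8 against 12.2 to 15.5) were the highest, and Gabarap (0.883; 383.3 against 398.3 to 400.3) was the lowest. In control replicate 4, Cldn5 (0.888; 9.88 against 11.2 to 11.4 FPKM), Slc4a1 (0.906; 0.79 against 0.906 to 0.918), Hsd17b10 (0.888; 14.8 against 19.4 to 19.98), Hsd3b6 (0.86; 28.6 against 88.9 to 98.7), B4galnt1 (0.89; 17.5 against 21.0 to 21.5) and Aldh2 (0.889; 40.4 against 58.7 to 61.0) were the lowest and Tssk2 (0.943; 800.8 against 725.3 to 729.5) was the highest. In control replicate 2, Prdx3 (0.94; 43.2 against 30.4 to 31.1 FPKM), Insl3 (0.925; 1188 against 972.9 to 989.1) and Prlr (0.838; 9.33 against 4.64 to 5.40) were the highest and Nr4a1 (0.91; 27.2 against 35.2 to 36.0) was the lowest. In valine replicate 3, Hsd3b6 (0.912; 12.5 against 27.6 to 29.0 FPKM) and Lhcgr (0.885; 0.344 against 1.22 to 1.34) were the lowest and Mob3b (0.898; 7.95 against 6.96 to 7.06) was the highest. In control replicate 1, Cfd (0.951; 29.8 against 0.325 to 1.77 FPKM) and Car3 (0.903; 14.6 against 0.261 to 1.65 FPKM) were the highest. Cfd was 0.152 FPKM in valine replicate 2 and 0 in the other 3 valine samples (ratio 1). In control replicate 3, the number of genes listed at 0 (0.874; 22705 against 21914 to 22014) was the highest. Prdx3 in valine replicate 1 (0.882; 21.2 against 24.6 to 25.0 FPKM) and Edem1 in valine replicate 4 (0.889; 8.501 against 8.91 to 8.96 FPKM) were the lowest.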

How the results depend on the processing

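The length and GC corrections were chosen after the data were seen; the causes of the changes below were not tested except where fewer samples or genes entered. Of the 16 lists past the camera threshold, 10 kept their call and direction under the 20 other settings compared apart from the estimated correlation, and 0 of the 35 lists passed with it. With it, adjusted p values were 0.132 for endothelial and lysosome, 0.16 for Leydig and macrophage, 0.164 for ribosomal proteins, 0.368 for round spermatid, and 0.161 for elongating spermatid, myoid, stroma, branched-chain catabolism, amino acid transport, mTORC1, p53, DNA methylation, one-carbon and cholesterol. Numbers of higher genes were 568 without a filter (42171 genes tested), 503 without the trend, 363 with equal totals, 398 with quantile normalisation and 475 after length correction; lower genes were 2022 with equal totals. With the replicate block, 581 were higher and 489 lower and no list lost its call. Same-numbered samples deviated together at r = -0.0167, -0.0401, 0.104 and 0.111, and not every sample correlated best with its own number. These values show no clear pairing by number, but they cannot exclude one. Without each sample (7 samples), 381 to 795 genes were higher and 461 to 802 lower, both under the main count by over 1.5 times without control replicate 1 (381, 461), control replicate 2 (466, 562) or valine replicates 1 (410, 489), 2 (593, 578), 3 (629, 647) and 4 (580, 614); list p values ranged from 0.0165 to 0.0927 for adipocyte (passing without control replicate 2, 0.0165, or 4, 0.0485), 0.018 to 0.0603 for p53 (not passing without control replicate 2, 0.0562, or valine replicate 4, 0.0603), 0.0331 to 0.154 for interferon (passing without control replicate 3) and 0.0485 to 0.148 for blood-testis barrier (passing without control replicate 4). Adipocyte passed without a filter (0.0136), with a pseudocount of 0.1 (0.0332) and after length correction (0.0306), and interferon without a filter (0.00113). With equal totals, autophagy (0.00866), m6A (0.00695), barrier (0.0247) and piRNA (0.0247) passed downward, as did autophagy (0.0371), barrier (0.0377) and piRNA (0.00548) with quantile normalisation, where round (0.47) and elongating spermatid (0.0654) did not pass. Mitochondrial transcripts turned from an uncalled upward direction to lower with quantile normalisation (0.01) and after length correction (0.0352). Length correction also ended the calls of round spermatid (0.057), mTORC1 (0.116), p53 (0.101), DNA methylation (0.12) and one-carbon (0.0509), and a filter at a mean of 5 FPKM those of p53 (0.172) and DNA methylation (0.0898). With fry, epididymis (0.0294), antioxidant (0.0464), barrier (0.0102) and interferon (0.0295) passed and round spermatid (0.0532) did not. Another 30 changes of direction concerned lists past the threshold in neither setting. Of 167 named genes, 0 reversed; between 0 and 51 fell short of the threshold in a setting, most without valine replicate 1. Robust moderation changes no camera test and gave 955 higher and 971 lower genes. The absolute depth was unknown, so counting error could not be set beside these values.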

Other observations

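The test of androgen-responsive genes was chosen after part of the data were seen. Gene families were also grouped by the letters that start their symbols (258 families of at least 8 tested genes; names below chosen after their values were seen). Of 19 aldehyde dehydrogenases 6 fell and none rose (camera adjusted p = 0.000638; adjusted p = 0.451 with an estimated correlation), among them Aldh1a7 (25.5 ± 7.39 to 6.49 ± 0.903 FPKM, SD, n = 4 per group), Aldh1a1, which makes retinoic acid (193.6 ± 44.7 to 78.4 ± 15.4 FPKM), and mitochondrial Aldh2 (54.9 ± 9.71 to 28.7 ± 1.99 FPKM). The Leydig list fell by more in the same samples (median -1.55). Among 12 lipid transporters of the Abca family 3 fell and none rose (camera adjusted p = 0.000733; adjusted p = 0.451 with an estimated correlation), with the cholesterol exporter Abca1 falling from 13.2 ± 2.84 to 4.75 ± 0.559 FPKM. Axonemal dynein heavy chains, which drive the sperm tail and are very long transcripts, had 3 falls among 14 (camera adjusted p = 0.00167; adjusted p = 0.451 with an estimated correlation), Dnah17 (95.0 ± 12.1 to 68.9 ± 5.15 FPKM) and Dnah2 (46.1 ± 5.14 to 35.3 ± 2.47 FPKM) among them; after length correction neither passed (limma adjusted p = 0.129 and 0.145).

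Some transcripts of mitochondrial proteins rose in the values as deposited. The length trend was not removed for the family counts below, so it stays a candidate explanation for these rises. Of 50 mitochondrial ribosomal proteins of the large subunit 9 rose and none fell (camera adjusted p = 0.000129; adjusted p = 0.451 with an estimated correlation; medians 0.17 as deposited and 0.06 with equal totals), with Mrpl20 rising from 69.6 ± 2.67 to 90.8 ± 2.85 FPKM and Mrpl47 from 25.5 ± 2.13 to 36.1 ± 4.19 FPKM. Of 15 Ndufa subunits of respiratory complex I 4 rose (camera adjusted p = 0.000316; adjusted p = 0.451 with an estimated correlation; medians 0.27 and 0.16), with Ndufa6 rising from 65.7 ± 0.936 to 84.8 ± 4.03 FPKM and Ndufa5 from 108.6 ± 7.54 to 138.4 ± 12.02 FPKM. The Mrps (2 of 31 rose, camera adjusted p = 0.124) and Ndufs families (0 of 9, camera adjusted p = 0.153) did not pass. Of 29 Spata genes, most of them spermatid transcripts, 7 rose (camera adjusted p = 0.00195; adjusted p = 0.568 with an estimated correlation), and Spata33 rose from 156.0 ± 4.18 to 217.0 ± 8.98 FPKM. In all 31 families passed with the preset correlation and 0 with an estimated correlation. By gene type, 107 of 2693 pseudogenes rose and 26 fell, and 136 of 4062 long noncoding or unconfirmed genes rose and 41 fell, while 705 of 14517 protein-coding genes rose and 896 fell.

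Lower androgen supply from Leydig cells was put forward as a hypothesis, since enzymes of testosterone synthesis fell. It would lower genes that Sertoli cells express in response to androgen. The mean of 6 such genes (Rhox5, Eppin, Drd4, Tubb3, Cldn3 and B4galnt1; Cldn3 is also in the barrier list and Rhox5 in the Sertoli list) was 0.135 higher with valine on the log2 scale (exact permutation p = 0.0286, the smallest these samples can give; higher in 4 of 4 samples), and 0.0235 higher with equal totals (exact permutation p = 0.571), so no fall was seen. Cldn3 (108.9 ± 4.24 to 136.3 ± 12.4 FPKM) and Tubb3 (30.4 ± 2.78 to 37.9 ± 1.02 FPKM) rose (limma adjusted p = 0.0277 and 0.0304), neither past the threshold with equal totals (limma adjusted p = 0.0724 and 0.123). Rhox5 had 14.7 ± 1.04 and 16.96 ± 0.975 FPKM, Eppin 63.3 ± 4.38 and 73.0 ± 6.13 FPKM, Drd4 6.01 ± 0.719 and 5.09 ± 1.10 FPKM, and B4galnt1 20.3 ± 1.91 and 20.3 ± 1.17 FPKM. Hormone levels were not analysed here.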
